A study of Mus musculus with 2 samples.

How the data were processed

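Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for Brd4 was carried out in 3T3-L1 cells, a mouse preadipocyte line that becomes fat cells when given a hormone cocktail. Brd4 is a bromodomain protein that binds acetylated histones, and MS417 is an inhibitor of the BET bromodomain family to which it belongs. Per the labels' protocols, cells were induced 2 days after confluence with 1 μM dexamethasone, 0.5 mM IBMX and 167 nM insulin, and chromatin was taken on day 5. The DMSO control library came from cells given 1 μL of DMSO per mL of medium, and the MS417 library from cells given 1 μM MS417 during differentiation. Each treatment had 1 library. Per the labels' protocols, fragments of 200 to 300 bp were cut from a gel and amplified over 16 PCR cycles.

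The data used were a single list of regions that the authors deposited for the pair of libraries, named as sensitive to MS417. Neither library had read counts, signal or a peak list of its own in the data used here, so the depth of both libraries is unknown and no level of Brd4 binding could be given for either treatment. The submitters' processing notes name CASAVA 1.4, Bowtie2, SICER 0.0.1 and the mouse build mm9, without saying what each was used for. The window, gap and threshold settings, any input control, and the rule by which a region counted as sensitive are not given in the sources used here. The deposited score is 0 in every region and the strand is plus in every region, so neither carries a measurement. All 23816 regions start and end on multiples of 200 bp, and the smallest gap between neighbours is 800 bp. The names number the regions without a hole. The last region on chromosome 1 ends at position 197010400, past the GRCm38 length of 195471971 bp and within the mm9 length of 197195432 bp. The coordinates below are therefore mm9, counted from 1.

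The gene table at hand was for GRCm38, another build, and no mm9 sequence was used. The planned assignment of regions to genes, gene parts and fixed gene lists, and the planned motif search, were not run. The planned summary of scores was not run because the score is constant. Of the rule for named items fixed before the data were examined, only the part without an annotation could be applied, which names the 10 stitched domains with the most region bases by their coordinates. The tests of the closing section that were chosen later are named there.

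Regions per Mb were computed over the assembled mm9 length of each chromosome, taken from GenomeInfoDb 1.38.1, with exact Poisson 95% intervals. Ratios of densities have exact (Clopper-Pearson) 95% intervals from the conditional binomial. Regions lie in clusters, so these intervals are too narrow; they cover counting error only and say nothing of a repeat of the experiment. The 2 mitochondrial regions were left out of the comparisons, which cover the 19 autosomes and X. Regions at most 12500 bp apart were stitched into domains, a distance often used for clusters of enhancers; a domain may hold a single region. The observed domains were set beside 100 random placements of the same region lengths between the first and last region of the same chromosome, with gaps of at least 800 bp. A second set of 100 placements, added after the data were seen, kept each region inside its bin of 5 Mb. Relations across chromosomes were not among the planned tests and were tested with 100000 two-sided permutations. On simulated data, a uniform set of 23814 regions gave 19778 domains, inside the 19623 to 19837 of fresh placements, and a set with planted clusters gave 18641, below the 19672 to 19864 of its placements. Alternatives were a minimum length, other stitching distances, merging of neighbours and bases in place of counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.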

Results

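Brd4 occupancy was profiled in differentiating 3T3-L1 adipocytes on day 5, in 1 library from DMSO-treated cells and 1 library from cells treated with 1 μM of the BET inhibitor MS417. The comparison asks where Brd4 binding differs between cells differentiated with and without the inhibitor. Because MS417 was given during differentiation, a direct response of binding cannot be told apart from a difference in how far the cells had differentiated. The data are the authors' list of 23816 MS417-sensitive regions made from these 2 libraries. With 1 library per treatment there is no replicate check, and the list gives no binding level, fold change or read depth for either treatment. Regions not called sensitive are not in the list used here, so the share of Brd4 sites that was sensitive cannot be stated. All values below describe this list, and no p-value compares the treatments.

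The listed MS417-sensitive regions were mostly several kb long. Length depends on the caller's settings, which are not given, and regions not called sensitive were not at hand for comparison. The 23814 nuclear regions had a median length of 4400 bp, with quartiles of 3400 and 6000 bp, on the 200 bp grid of the list. The shortest region was 400 bp and 631 regions (2.65%) were shorter than 2 kb. At the other end, 1158 regions (4.86%, exact 95% interval 4.59 to 5.14%, counting error only) were longer than 10 kb and held 13.3% of all region bases. Only 27 regions exceeded 25 kb and 4 exceeded 50 kb. Together the nuclear regions covered 119.7 Mb, or 4.54% of the assembled autosomes and X chromosome.

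The regions were spread very unevenly over the chromosomes. Chromosome 19 had the highest density, with 1427 regions or 23.3 per Mb (95% interval 22.1 to 24.5), against 9.02 per Mb over all nuclear chromosomes. Chromosome 2 carried the most regions, 3667 or 20.2 per Mb (19.5 to 20.8), which is 15.4% of the list on 6.89% of the assembly. Chromosome 11 had 19.8 regions per Mb (18.97 to 20.6) and chromosome 6 had 18.6 (17.9 to 19.3). Chromosome 17 had 16.7 regions per Mb (15.9 to 17.6) and chromosome 8 had 14.7 (14.03 to 15.3). These 6 chromosomes held 58.0% of the regions on 28.1% of the assembly.

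Chromosomes 12 and X were almost free of listed regions. Chromosome 12 had 77 regions, or 0.635 per Mb (0.501 to 0.794), and its density was 36.6-fold below that of chromosome 19 (95% interval 29.1 to 46.7). The X chromosome had 35 regions, or 0.210 per Mb (0.146 to 0.292), and chromosome 12 was 3.02-fold denser than X (2.00 to 4.65). No region was listed on Y. Low densities were also found on chromosome 18 (2.77 per Mb, 2.43 to 3.13), chromosome 14 (3.16 per Mb, 2.85 to 3.48), chromosome 7 (3.62 per Mb, 3.32 to 3.93) and chromosome 4 (4.02 per Mb, 3.71 to 4.35). Chromosome 2 was 5.57-fold denser than chromosome 7 (5.10 to 6.11). The difference between chromosomes 19 and 12 was 18.1-fold (14.3 to 23.2) when stitched domains were counted in place of regions.

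**Figure D1:**
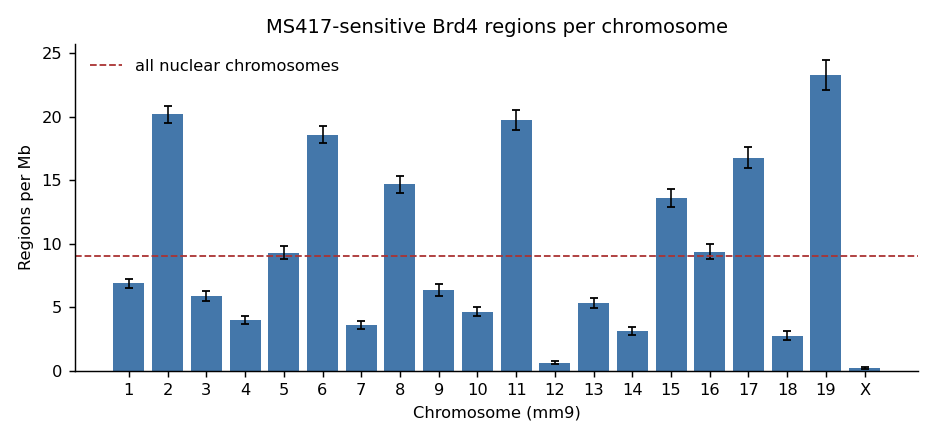
Regions per Mb of assembled chromosome (y axis) for each nuclear chromosome of mm9 (x axis). Bars are the densities, whiskers are exact Poisson 95% intervals for counting error, and the dashed line is the density over all nuclear chromosomes, 9.02 per Mb; chromosomes 12 (0.635 per Mb) and X (0.210 per Mb) stand at the bottom and chromosome 19 (23.3 per Mb) at the top.

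The contrast was seen in most bins of 5 Mb, though not in all. The 36 full bins of chromosome 2 held a median of 103 regions and the 29 bins of chromosome 6 a median of 80. Chromosome 12 had a median of 1.5 regions per bin, no region in 7 of its 24 bins, and at most 19 regions in a bin, at 80000001 to 85000000. Fewer than 19 regions lay in 5 bins of chromosome 2, the lowest with 2 regions (85000001 to 90000000), and in 2 bins of chromosome 6. On X, 25 of 33 bins were empty, and 28 of the 35 regions lay between positions 5838601 and 18744400. The next region on X followed after an empty stretch of 52.0 Mb. The longest empty stretches between neighbouring autosomal regions were 15.8 Mb on chromosome 12 (9585601 to 25392200) and 14.9 Mb on chromosome 7 (35828401 to 50698400). The densest bin in the genome was on chromosome 11 (75000001 to 80000000), with 231 regions, followed by chromosome 2 (45000001 to 50000000), with 227, and chromosome 17 (80000001 to 85000000), with 217.

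**Figure D2:**
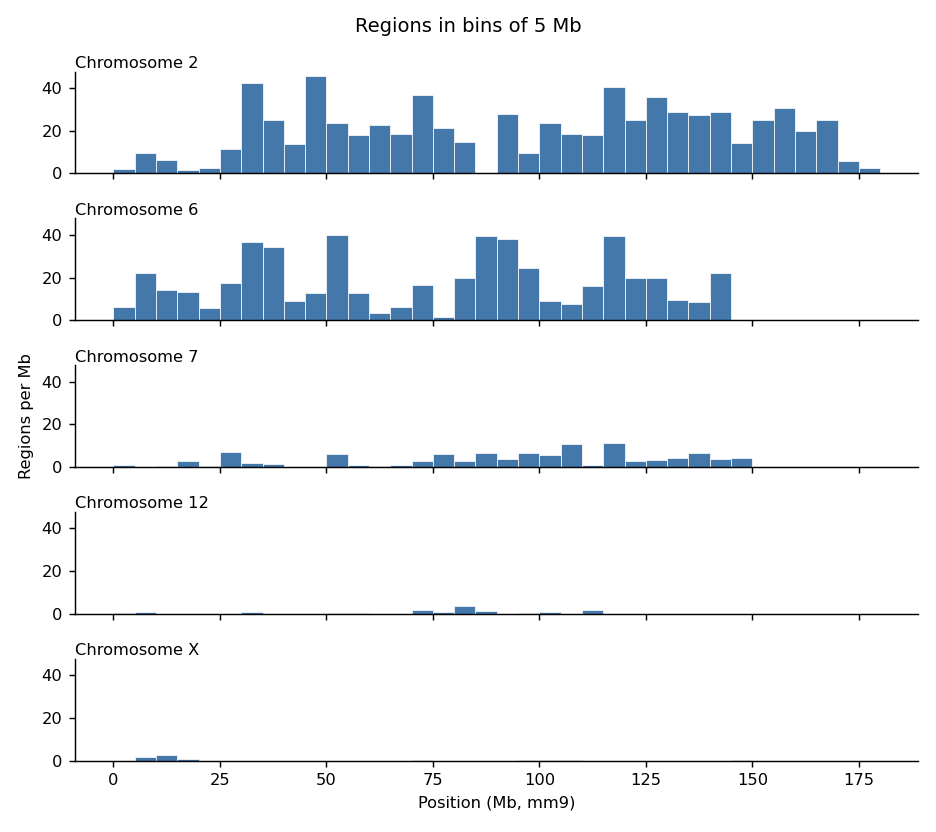
Regions per Mb (y axis, shared scale) in consecutive bins of 5 Mb along chromosomes 2, 6, 7, 12 and X (x axis, position in Mb, mm9). Each bar is 1 bin; the highest bin of chromosome 2 held 227 regions, that of chromosome 12 held 19 and that of X held 14.

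Regions were also longer where they were denser. The median length was 4800 bp on chromosome 19 and 4600 bp on chromosome 6, against 4000 bp on chromosomes 12 and X. The 90th percentile of length was 10800 bp on chromosome 19 and 9400 bp on chromosome 6, against 5800 bp on chromosome 12 and 5320 bp on X. Across the 20 chromosomes, which are not replicates, density and the 90th percentile of length were correlated (Pearson's r = 0.937, Spearman's rho = 0.889, permutation p = 1e-05 for each, the smallest that the permutations can give). Density and median length gave r = 0.877 and rho = 0.873 with the same permutation p. These were the 2 relations computed, neither of them planned, and the Benjamini-Hochberg adjusted value was 1e-05 for each. Without chromosomes 19 and 2, the farthest from the median density, r was 0.923 for the 90th percentile and 0.862 for the median. Density and length come from the same call of regions, so their relation may reflect the calling as well as Brd4 binding.

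**Figure D3:**
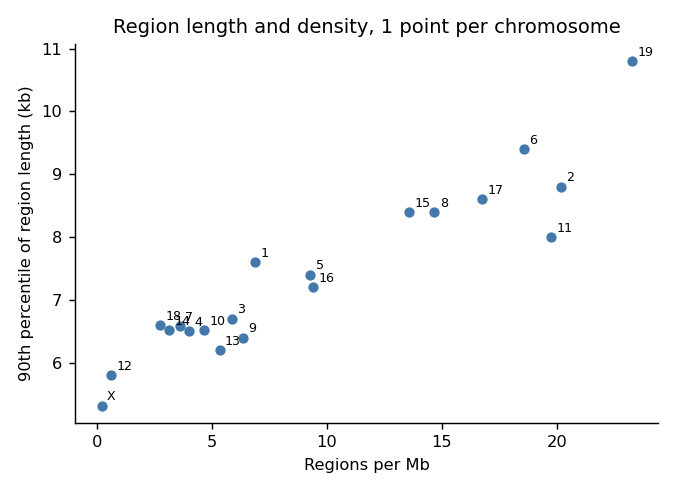
The 90th percentile of region length in kb (y axis, not starting at 0) against regions per Mb (x axis), with 1 labelled point per chromosome. The points rise together (Pearson's r = 0.937 over 20 chromosomes), from X at the lower left to chromosome 19 at the upper right.

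Regions occurred in groups. Stitching neighbouring regions within a fixed distance gave 14879 domains, of which 10162 held a single region. The 4717 domains of 2 or more regions contained 13652 regions, or 57.3% of the list. Placing the same regions at random on their chromosomes gave 19770 ± 46.9 domains (SD over 100 placements) and never fewer than 19665. Domains of 5 or more regions numbered 531, against a mean of 33.4 and a highest value of 49 in the placements. Placements that kept each region inside its bin of 5 Mb gave 18561 ± 52.1 domains and a mean of 128.6 domains of 5 or more regions, with a highest value of 147. Both kinds of placement moved each listed region on its own, so a stretch of binding split by the caller would count as grouped regions. Whether such splits occurred is not known, and no placement was run with short gaps joined. The observed number of domains lay below every placement along the chromosome on 18 of the 20 chromosomes. The exceptions were chromosome 12 and X, where the comparison could show little. Placements gave 73 to 77 domains for the 77 regions of chromosome 12, and 34 to 35 for the 35 regions of X. Domains of 5 or more regions were most numerous on chromosomes 2 (129 domains, placement mean 9.22) and 6 (101 domains, placement mean 5.73). As a share of a chromosome's domains they were highest on chromosome 19 (8.36%), against 7.14% on chromosome 6 and 6.78% on chromosome 2. None was found on chromosomes 7, 12, 13, 14, 18 or X, where placements gave a mean of at most 0.01.

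The domains with the most region bases included long, nearly continuous stretches on chromosomes 10 and 1. On chromosome 10, the domain from 116752201 to 117238000 held 478200 bp of region in 3 regions and was 98.4% covered. It contained the longest regions of the list, of 310400 bp (116927601 to 117238000) and 152400 bp (116752201 to 116904600). No region lay in the 100 kb on either side of it. On chromosome 1, 3 of the 10 leading domains lay next to one another. They spanned 189359601 to 189509400 (114000 bp of region), 189526401 to 189828200 (283800 bp) and 189842401 to 190285400 (391800 bp), separated by 17000 and 14200 bp. As a single block of 925.8 kb they held 49 regions and were 85.3% covered, with 0% of the 100 kb before it and 13.6% of the 100 kb after it covered.

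**Figure D4:**
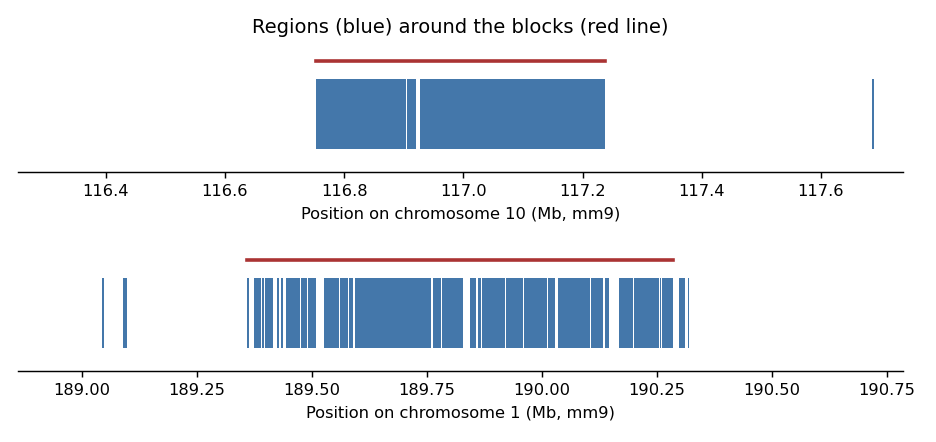
Listed regions (blue boxes, drawn to scale) in the blocks of chromosome 10 (upper) and chromosome 1 (lower) with the sequence on each side, by position in Mb (mm9). Red lines mark the blocks of 485.8 kb and 925.8 kb; boxes have no height scale, and regions cover 98.4% and 85.3% of the blocks.

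Of the other 6 of these 10 domains, 5 were covered to a smaller share than those on chromosomes 10 and 1. The chromosome 2 domain (77710601 to 77851000) held 119400 bp in 6 regions and was 85.0% covered. The pair on chromosome 6 held 114000 bp in 17 regions (86375001 to 86556800) and 89600 bp in 15 regions (38718201 to 38856400), and were 62.7% and 64.8% covered. The pair on chromosome 19 held 109600 bp in 14 regions (4364001 to 4522400) and 91800 bp in 11 regions (41973001 to 42106000), and were 69.2% and 69.0% covered. The chromosome 17 domain (81153201 to 81331600) held 103600 bp in 20 regions and was 58.1% covered. Genes at these positions were not assigned, because no mm9 annotation was used here.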

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

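Chromosome 19 stayed denser than chromosome 12 for longer regions, bases covered and domains, and domains stayed fewer than in random placements under each setting whose ratio is given below, while sizes moved. Keeping only regions of at least the median length of 4400 bp left 12261 regions, which form 9253 domains. Under it the density of chromosome 19 over chromosome 12 was 50.8-fold; it was 51.5-fold by bases covered and 18.1-fold by domains, against 36.6-fold. The share of regions on a chromosome moved by 0.777 to 1.60 times over these alternatives. Merging touching regions could change nothing, as the smallest gap is 800 bp. Joining regions at most 1400 bp apart, an alternative chosen after seeing the data, left 21592 regions. The ratio of observed to randomly placed domains was 0.753, and was 0.852 at a stitching distance of 5000 bp, 0.650 at 25000 bp, 0.834 for the longer regions and 0.802 when placement was kept inside 5 Mb bins, and 0.754 without the blocks of chromosomes 1 and 10; the last 2 and the count by domains were also added later. Of the 10 leading domains, 8 changed their region bases by over 1.5 times at 5000 bp, 4 did so at 25000 bp and 4 when only the longer regions were kept. No paired analysis was possible because each treatment has 1 library and the list holds no value per library. The alternatives chosen for genes, gene lists, gene parts, motifs and scores were not run. The list gives no depth, so nothing can be said of sites that missed the authors' threshold.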

Other observations

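Of the tests in this part, those of lost rows, copy number, the blocks and the short gaps were chosen after the result was seen, and the count by stitched domains and the shift of chromosome borders were added after the uneven densities were seen. The list also holds 2 regions on the mitochondrial genome, 1 to 6600 and 10801 to 16200, which cover 73.6% of its 16299 bp, against 4.54% of the nuclear assembly. Without an input library it cannot be told whether these mitochondrial regions reflect Brd4 binding at all. The 31 domains of at least 100 kb outside the blocks of chromosomes 1 and 10 had a median of 59.8% of their length covered by regions, and the highest, on chromosome 2, was 85.0% covered.

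The near absence of regions from chromosomes 12 and X, beside the high densities of chromosomes 2, 6, 11 and 19, is the pattern that most calls for a second look. Rows lost after the regions were numbered are argued against, because the running names have 0 holes, while a loss before numbering stays open. Separate counting of neighbouring regions carried part of the contrast: chromosomes 19 and 12 differed 36.6-fold by regions and 18.1-fold by stitched domains. Stitching could hardly remove the rest, so it does not decide. Chromosome 12 kept 77 domains for 77 regions, and random placement on chromosome 19 still gave a mean of 1012 domains. Local structure alone is also argued against: bins of 5 Mb at least 50 Mb apart on the same autosome correlated at r = 0.336 on the scale of log2(regions + 1), above the highest of 485 shifts of the chromosome borders along the genome (0.285), and r was 0.271 to 0.404 with each autosome left out in turn, lowest without chromosome 12. In simulations over the same 486 bins, this test passed its 95th percentile in 40 of 50 sets with a 3-fold chromosome effect and in 3 of 50 without. The simulated local structure was of shorter range than 50 Mb, so the rate without an effect does not cover structure of longer range. A hypothesis is that chromosome copy number in this established line, a kind often aneuploid, may set how many sites pass the caller's threshold. On the scale of log2(regions + 1), 46.5% of the variance between bins lay between autosomes, X not included. Any cause of uneven autosomes could give such a share, so it does not decide. Without an input library, copy number cannot be told apart from a true difference in the response to MS417, which was untested. Gene content per chromosome needs no input library and was also untested.

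The near-continuous blocks of chromosomes 10 and 1 were picked for the share of their length that regions cover, so that share cannot decide between explanations. The chromosome 10 block was 98.4% covered, 4.40 percentage points above the highest of the 34 other domains of at least 100 kb, which lies in the chromosome 1 block; the latter as a whole was 85.3% covered, a difference of -13.1 points from the chromosome 10 block and close to the chromosome 2 domain, whose sides were 0% and 5.2% covered. Regions covered 0% of the 100 kb on each side of the chromosome 10 block, and 0 of those 34 domains had both sides empty, though 7 had under 20% covered on each side, the limit set for a gained segment, and chromosome 10 is also among the sparser chromosomes. A gained DNA segment is a candidate explanation. Neither block was made only of regions of ordinary length. The chromosome 10 block held regions of 310400 and 152400 bp, against a 99th percentile of 15000 bp over the nuclear regions. Among the 49 regions of the chromosome 1 block, the longest were 48000, 45000 and 40400 bp. Dense sites joined into long regions by the caller stay open for both blocks. These explanations cannot be told apart for either block without reads from an input library, and a repeat-rich or wrongly assembled stretch was not tested.

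Short gaps were frequent. Gaps of 800 to 1400 bp numbered 2222, against a mean of 322.2 and a highest value of 365 in 100 placements inside 5 Mb bins; regions cluster inside such bins and the window was picked for its excess, so this count does not decide whether the spacing is special. They were 3.85 times as many as gaps of 2000 to 2600 bp, and 1018 of them were exactly 800 bp, the smallest gap in the list. A candidate explanation is that the caller's joining distance split longer stretches of binding, since no gap was below 800 bp and many lay at that limit. Pairs of neighbouring sites stay open, and the list alone does not decide between these explanations.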
